A study of Homo sapiens with 131 samples.

How the data were processed

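Gene expression in lung and lung tumor samples from 32 patients with non-small cell lung cancer was measured on 131 Affymetrix Human Gene ST arrays. Per the labels, tissue was taken by macrodissection, by laser capture microdissection followed by amplification of the RNA with a Pico kit, or by macrodissection followed by the same amplification. The 3 sample types are called macrodissected, microdissected and amplified macrodissected below. The macrodissected type was prepared with another amplification kit, so the word amplified below refers to the Pico amplification. For the amplified macrodissected samples, the sample titles name the Pico amplification and the labelling protocol names another kit, and the titles were followed here. Per the labels, tissues were tumor, non-tumor lung and, among the microdissected samples, non-tumor bronchial tissue, and tumors were adenocarcinoma, squamous cell carcinoma or adenosquamous carcinoma.

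The deposited value table holds log2 probe set values, which the authors made with RMA in Affymetrix Expression Console per the submitters' processing notes. The version and settings of these tools are not given in the sources used here. The median of the deposited log2 values over all probe sets of an array lay between 6.98 and 7.12 for macrodissected, 4.51 and 4.71 for microdissected and 4.36 and 4.55 for amplified macrodissected samples. The values of the 3 sample types were therefore not treated as being on 1 scale. Sample types were compared only through the tumor minus non-tumor difference of the same patient. A pair of planned comparisons of levels between microdissected and amplified macrodissected tissue, in tumors and in non-tumor lung, was not made for this reason. The number of arrays limits the precision of every value.

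The authors' deposited tables of tumor against non-tumor genes give a signed fold change, negative for lower genes. Their second column of values is a p-value, adjusted by the authors with the Benjamini-Hochberg method. Per the authors' accompanying text, genes were selected with limma at an adjusted p-value of at most 0.05 and a fold difference of at least 2. Whether the authors paired the patients is not given in the sources used here. The deposited lists of shared and private probe numbers were not used here, because the same overlaps were computed from the 3 tables.

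All 33297 probe sets were tested, with no filter on dim ones. The annotation used here names exactly 1 gene for 19460 of them (18417 distinct symbols) and several genes for 1754, and 12083 are not listed or have no symbol. Only probe sets naming 1 gene were used for named genes and gene lists. For a gene with several probe sets, the one with the highest mean over all arrays was taken. Genes with near-identical copies, such as histones, SPRR2A and CYP2B7P, are named with the reserve that a probe set can also measure a copy.

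Differences were tested with limma 3.58.1 (linear fit and moderated statistics, no intensity trend, no robust prior, two-sided) in R 4.3.3, and tables were read with the data.table package, version 1.17.8. The p-values were adjusted with the Benjamini-Hochberg method over all probe sets of a comparison, and an adjusted p under 0.05 was called. The patient was a fixed block wherever a patient gave both tissues, as the sample titles pair the arrays. The 3 microdissected tissues were fitted together. The 2 arrays per tissue of 1 patient were averaged first. Squamous cell carcinoma was compared with adenocarcinoma in tumors of each sample type and in macrodissected non-tumor lung, without adenosquamous tumors. An interaction compared the tumor minus non-tumor difference of each patient between both histologies. The tumor minus non-tumor differences were also compared between pairs of sample types within patients. The pairing was checked by correlating each tumor with the non-tumor tissue of its own patient. Correlations were taken across genes after centring on the mean of each tissue. Their median was 0.43 for macrodissected, 0.09 for microdissected and 0.22 for amplified macrodissected pairs. For tissues of different patients it was -0.10, -0.01 and -0.08. The centring did not remove the array sets described below, which both tissues of a patient share. For macrodissected and amplified macrodissected pairs the check therefore cannot tell the patient from the set. The tumor was closest to the non-tumor tissue of its own patient in 17 of 30 macrodissected, 3 of 15 microdissected and 7 of 10 amplified macrodissected pairs.

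The procedure was tested on simulated data with 50 changed probe sets per size of change. Changes of 2-fold were called in 100% of simulated probe sets for macrodissected tumor against non-tumor lung, 86% for the microdissected, 78% for the amplified macrodissected and 84% for the macrodissected histology comparison. The same change was called in 40% and 32% for the comparisons with bronchial samples, 62% and 36% for the microdissected and amplified histology comparisons, 92% for non-tumor lung and 88% for the interaction. Between sample types it was called in 30% (microdissected minus amplified), 70% (microdissected minus macrodissected) and 78% (amplified minus macrodissected). Between 3 and 15 unchanged probe sets were called in each. They made up 1.7% of calls for non-tumor lung, the lowest share, and 10.1% for the microdissected histology comparison, the highest. The simulated noise was independent between genes, unlike real data.

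A total of 24 gene lists were fixed: markers of alveolar type I and type II, ciliated, airway secretory, basal and squamous and glandular epithelial cells, endothelial cells, fibroblasts and tumor matrix, smooth muscle cells, macrophages, T and NK cells, B and plasma cells, mast cells, neutrophils and erythroid cells, and genes of proliferation, hypoxia and glycolysis, matrix metalloproteinases, NRF2 targets, MHC class II, the interferon response, immediate early and heat shock genes, the mitochondrial respiratory chain and replication-dependent histones. AGR2 stands in the secretory and the glandular list, and MMP11 and MMP14 in the matrix and the metalloproteinase list. Lists were tested with fry of limma on the fit of each comparison, adjusted with the Benjamini-Hochberg method over the 24 lists, and again with camera of limma with an estimated correlation between the genes of a list. The directional p of fry tests whether the genes of a list move, on balance, one way, and its mixed p whether they change in either direction. Neither compares a list with other genes or lists. Camera does so: it tests whether the genes of a list move more than the other genes. Values given below with an estimated correlation are those of camera. A list can therefore pass fry and not camera for a reason other than the correlation. Members were also counted over all probe sets and adjusted over the list alone.

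The comparisons, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule takes the 10 largest positive and 10 largest negative differences among called genes with the same direction in at least 90% of the patients with both tissues, for the 3 comparisons of tumor with non-tumor lung. It takes the 5 and 5 largest for every other comparison. From each list it takes the first 2 measured members as written and the 2 with the smallest p. The alternatives fixed with them were the patient as no block or as a random effect, leaving out the third of the probe sets with the lowest mean, quantile normalization, an intensity trend with a robust prior, a threshold of 0.01, leaving out adenosquamous patients, using the first array of the patient with 2, leaving out single patients in groups of 4 or 5, and camera. Alternatives chosen after seeing the data were probe sets naming 1 gene only, leaving out patients whose difference ran against the others, leaving out 1 bronchial array low in ciliated genes, and fits within or across array sets seen in the values. Exact sign-flip tests across patients, two-sided, were used for list means, and their p-values, named exact p, were not adjusted over the lists. Samples in groups of 4 to 10 were checked for values far from the others with Dixon's test. The comparisons were repeated on other splits of the same samples, 100 drawn, or all 64 or 16 where there were no more.

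A total of 2 microdissected arrays were left out of every comparison, because their labels do not settle the tissue. Adenosquamous tumors were left out of the histology comparisons. Per the labels, pairs of tissues come from the same donor.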

Results

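The samples came from 32 patients with non-small cell lung cancer and were taken in 3 ways. Macrodissected tissue gave 64 arrays, and 30 patients had both tumor and non-tumor lung, 18 with adenocarcinoma, 10 with squamous cell carcinoma and 2 with adenosquamous carcinoma. Laser capture microdissection, in which chosen areas are cut out of a tissue section under the microscope, gave 47 arrays of 25 patients. Of these, 21 patients had a tumor sample, 19 non-tumor lung and 5 non-tumor bronchial tissue, and 15 had both tumor and non-tumor lung. Macrodissected tissue whose RNA was amplified like that of the microdissected samples gave 20 arrays of 10 patients, each with tumor and non-tumor lung (4 with adenocarcinoma, 6 with squamous cell carcinoma). All differences below are on the log2 scale with the standard error (SE) of the limma fit, and every p is adjusted unless named otherwise.

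The macrodissected arrays fell into 2 sets in their values. On the first principal component of the non-tumor samples (38.1% of the variance), the gap between the sets took a share of 0.71 of the range and the next largest gap 0.06. Set 1 held 16 patients (8 with adenocarcinoma, 8 with squamous cell carcinoma) and set 2 held 16 (11, 3 and 2 with adenosquamous carcinoma), without a detectable link to histology (Fisher's exact p = 0.142). Between the sets, which were defined from these values, 14520 probe sets differed in tumors and 18162 in non-tumor lung. The difference between the sets correlated across genes, which are not independent replicates, at 0.924 between macrodissected tumor and non-tumor tissue. With the same split of the patients it correlated at 0.019 in microdissected tumors and 0.002 in microdissected non-tumor lung. In the deposited order, the 34 arrays of set 1 and the 30 of set 2 formed 2 unbroken runs. The split thus follows the order of the macrodissected arrays and did not recur in microdissected tissue of the same patients. The labels used here name no batch, and the cause was not tested. The amplified macrodissected arrays fell into 2 sets as well, 1 with 6 patients (4 with adenocarcinoma) and 1 with 4 patients (all with squamous cell carcinoma). Comparisons of tumor with non-tumor lung are within patients, and values within the sets are given beside the pooled ones.

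**Figure D1:**
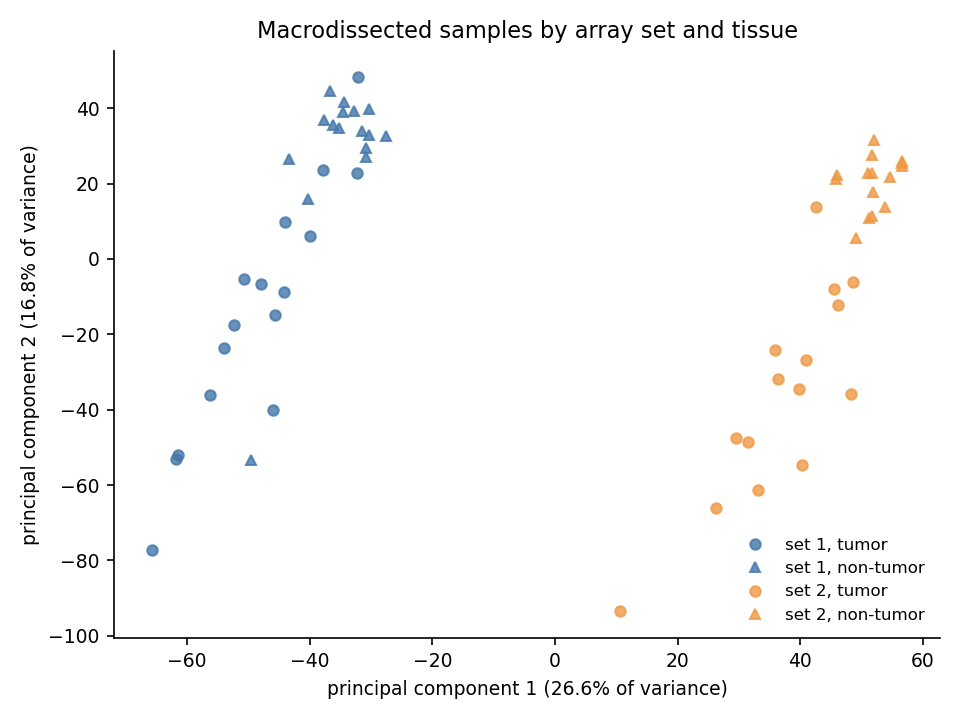
Scores of macrodissected samples on the first (26.6% of the variance) and second (16.8%) principal component, in arbitrary units, each point being 1 sample, with marks for tumor and non-tumor lung and colours for the array set. The 2 array sets separate on the first component, each with tumor and non-tumor samples.

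Macrodissected tumors differed from non-tumor lung of the same patient in genes of the alveolar wall, blood vessels, cell division and matrix turnover. SPP1, which encodes the secreted phosphoprotein osteopontin, rose 8.75-fold (3.13 ± 0.41, n = 30 pairs, p = 2.99e-06, higher in 28 of 30 patients). FABP4, a fatty acid binding protein of alveolar macrophages and capillary endothelium, fell 7.65-fold (-2.94 ± 0.36, p = 1.41e-06, lower in 28 of 30). The alveolar type I receptor AGER fell 5.28-fold (-2.40 ± 0.33, p = 4.69e-06, lower in 28 of 30), and the surfactant gene SFTPC 4.06-fold (-2.02 ± 0.43, p = 0.000635, lower in 27 of 30). The collagenase MMP13 rose 3.35-fold (1.75 ± 0.39, p = 0.000978) and the DNA topoisomerase TOP2A of dividing cells 3.22-fold (1.69 ± 0.25, p = 1.25e-05). The genes named are those with the largest differences among called genes with 1 direction in at least 90% of patients, so genes that moved more in fewer patients, such as MMP12, are not among them. The others that rose were SPINK1, the glucose transporter SLC2A1 (1.62 ± 0.27), the cystine transporter SLC7A11 (1.51 ± 0.24), the mitotic genes ANLN, DLGAP5 and TPX2, and the histone H2BC14. The others that fell were the serotonin transporter SLC6A4 (-2.58 ± 0.44), TMEM100, CPB2, the Wnt inhibitor WIF1 (-2.13 ± 0.37), the ficolin FCN3, RTKN2 and the alcohol dehydrogenase ADH1B.

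All 21 measured endothelial genes fell in macrodissected tumors (median -1.10, p = 5.52e-07), among them TIE1 (-1.05 ± 0.13), S1PR1 (-1.10 ± 0.13) and CDH5 (-1.39 ± 0.19). Of 11 alveolar type I genes 8 fell (median -1.32, p = 1.03e-05), with CAV1 at -1.32 ± 0.24 and EMP2 at -1.16 ± 0.16. All 10 smooth muscle genes fell (median -0.75, p = 2.38e-05), among them DES (-1.20 ± 0.17) and LMOD1 (-0.77 ± 0.13). Macrophage genes fell in 15 of 17 (median -0.48, p = 5.6e-05). Mast cell genes fell in 4 of 7 (median -0.69, p = 3.41e-05), with GATA2 at -0.80 ± 0.10. Neutrophil genes fell in 7 of 9 (median -0.69, p = 7.56e-05), with FPR2 at -1.20 ± 0.13. Of 15 immediate early and heat shock genes 13 fell and 1 rose (median -0.66, p = 0.000101), and KLF4 lay at -1.42 ± 0.24. For each of these 7 lists the adjusted p = 0.128 with an estimated correlation. Alveolar type II genes fell in 7 of 13 (9 adjusted over the list alone, median -0.79, p = 0.00102, and adjusted p = 0.158 with an estimated correlation), with ABCA3 at -1.26 ± 0.24 and SFTPB, which did not pass, at -0.79 ± 0.35. Ciliated genes fell in 13 of 19 (16 adjusted over the list alone, median -0.58, p = 0.0124, and adjusted p = 0.297 with an estimated correlation). Erythroid genes fell in 4 of 6 (median -0.45, p = 0.00231, and adjusted p = 0.2 with an estimated correlation), led by HBB at -1.29 ± 0.29.

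All 34 measured proliferation genes rose in macrodissected tumors (median 1.05, p = 2.38e-05), among them MKI67 (1.30 ± 0.18) and BUB1 (1.26 ± 0.18). All 9 matrix metalloproteinases rose (median 1.32, p = 1.03e-05), led by MMP12 (2.46 ± 0.42) and MMP1 (2.14 ± 0.41). Targets of NRF2, the regulator of the antioxidant response, rose in 13 of 16 (median 0.61, p = 3.41e-05), with NQO1 at 1.47 ± 0.23. Genes of the mitochondrial respiratory chain rose in 10 of 14 (median 0.16, p = 3.41e-05), with COX7B at 0.54 ± 0.10. For these 4 lists the adjusted p = 0.128 with an estimated correlation. All 14 histone genes rose (median 0.68, p = 5.16e-05, and adjusted p = 0.129 with an estimated correlation). Hypoxia and glycolysis genes rose in 12 of 17 and fell in 1 (median 0.49, p = 6.39e-05, and adjusted p = 0.15 with an estimated correlation), with ENO1 at 0.59 ± 0.10. Basal and squamous genes rose in 10 of 17 (12 adjusted over the list alone, median 0.87, p = 0.0058, and adjusted p = 0.307 with an estimated correlation), with SOX2 at 1.14 ± 0.28 and KRT15 at 1.06 ± 0.28. Genes of fibroblasts and tumor matrix rose in 13 of 21 and fell in 3 (median 0.52, p = 0.0124, and adjusted p = 0.39 with an estimated correlation), with COL10A1 at 1.47 ± 0.23, higher in 26 of 30 patients, and MMP11 at 1.32 ± 0.23. B and plasma cell genes rose in 5 of 10 (median 0.46, p = 0.0133, and adjusted p = 0.386 with an estimated correlation), with MS4A1 at 0.95 ± 0.27 and CD79A at 0.89 ± 0.20.

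The other 5 lists did not pass in macrodissected tumors. Airway secretory genes had 4 members that rose, such as AGR2 (1.05 ± 0.28), and 2 that fell, SCGB1A1 (-1.17 ± 0.39) being the larger (median -0.08, mean 0.09 and an upward test, p = 0.62). Glandular genes had 5 that rose and 1 that fell of 15 (median 0.24, p = 0.0747). T and NK cell genes had 6 of 14 that fell, with KLRF1 at -0.87 ± 0.17 (median -0.07, p = 0.0861). MHC class II genes (median -0.17, p = 0.119) and interferon response genes, of which 3 fell (median -0.12, p = 0.563), did not pass either. In limma, 9745 of 33297 probe sets were called, 5393 higher and 4352 lower, naming 6947 distinct genes, and 141 of them rose and 292 fell by 2-fold or more. The tumor minus non-tumor difference of 2 of the 30 patients ran against that of the others (correlation across genes -0.62 and -0.48), and 11676 probe sets were called without them. Within array set 1 (16 pairs) 827 were called, 312 higher and 515 lower, and within set 2 (14 pairs) 7656, 4113 higher and 3543 lower, with endothelial medians of -1.02 and -1.19 and proliferation medians of 0.99 and 0.95. Both patients whose difference ran against the others lie in set 1, and no fit within set 1 was run without them. The basal and squamous list passed in set 1 (median 1.01, p = 0.0416) and not in set 2 (0.48, p = 0.0876). The ciliated list did not pass in set 2 (-0.52, p = 0.165), the B and plasma cell and erythroid lists not in set 1 (0.43, p = 0.283, and -0.48, p = 0.0729), and the matrix list in neither (0.57, p = 0.0636, and 0.53, p = 0.162). The glandular list passed in set 2 alone (0.61, p = 0.00217, against 0.00, p = 0.868). The pairs of set 1 held 8 squamous cell carcinomas and 8 adenocarcinomas, those of set 2 held 2 and 10. For the basal and squamous and the glandular list, which differ between the histologies, set and histology can therefore not be told apart here.

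**Figure D2:**
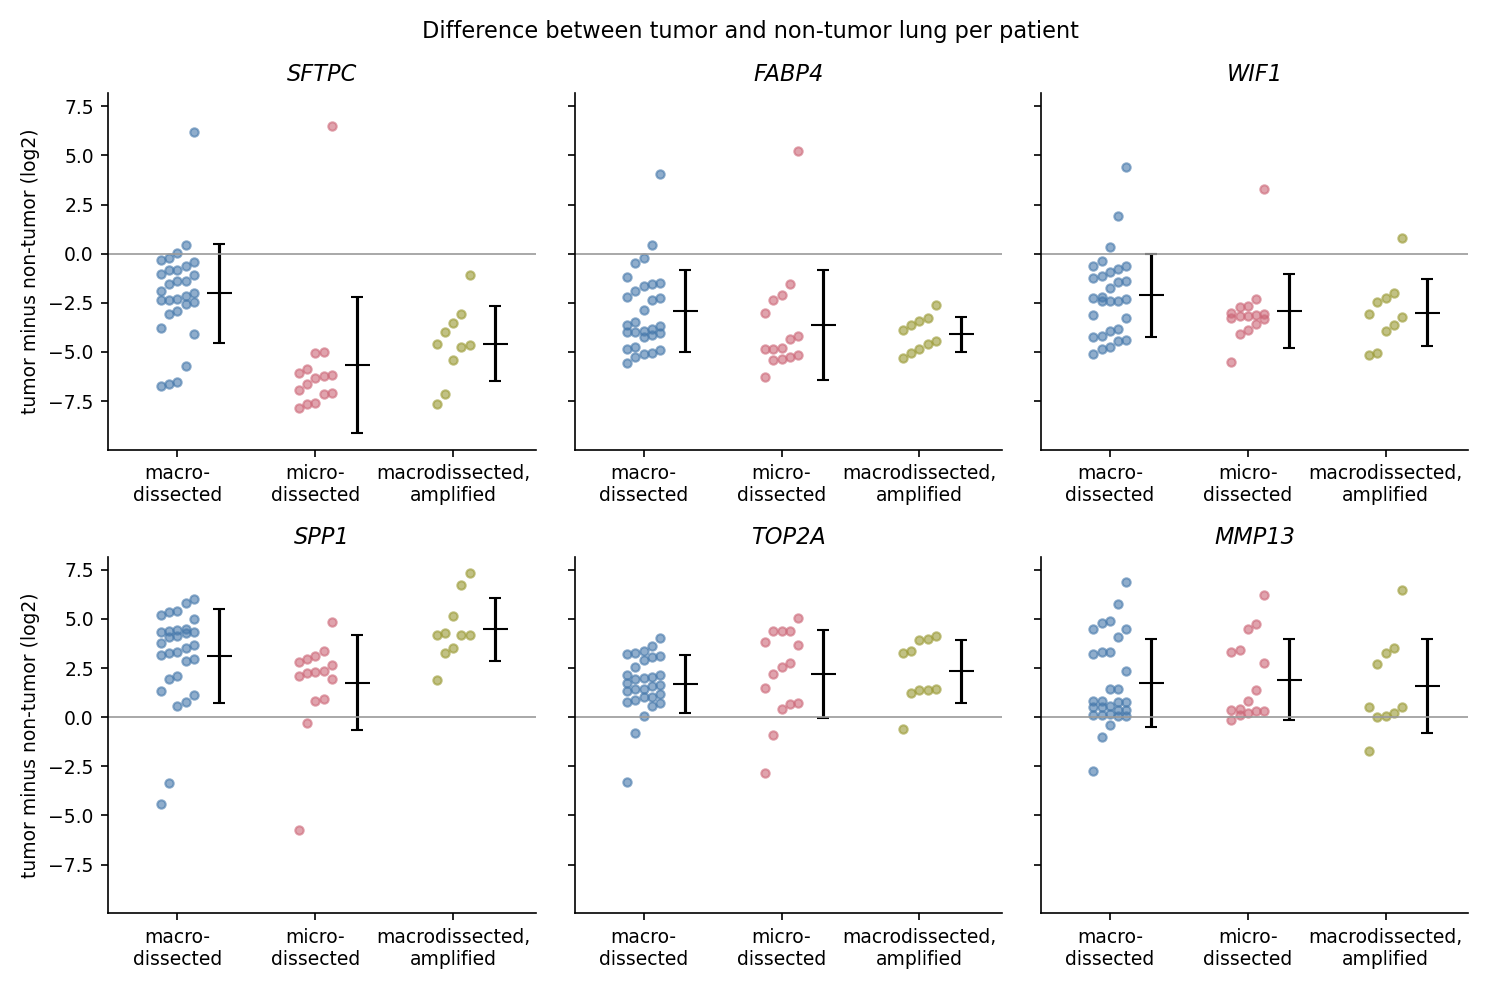
Tumor minus non-tumor difference (log2) of 6 genes in each patient (points) by sample type, with the mean and SD as bars. Mean SFTPC differences were -2.02 in 30 macrodissected, -5.67 in 15 microdissected and -4.59 in 10 amplified macrodissected pairs, and mean SPP1 differences 3.13, 1.77 and 4.47 (without the 2 macrodissected and 1 microdissected pairs that ran against the others, SFTPC -2.40 and -6.54 and SPP1 3.63 and 2.30).

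Microdissected tumors had lower levels of alveolar, endothelial and macrophage genes than microdissected non-tumor lung. SFTPC fell 46.4-fold (-5.54 ± 0.77, n = 15 pairs, p = 0.00111, lower in 14 of 15). The hemoglobin gene HBB fell 19.7-fold (-4.30 ± 0.56, p = 0.00111, lower in 14 of 15). FABP4 fell 11.7-fold (-3.55 ± 0.61). Without the patient whose difference ran against the others the differences were -6.37 for SFTPC and -4.15 for FABP4. The macrophage mannose receptor MRC1 fell 10.8-fold (-3.43 ± 0.50) and the endothelial adhesion molecule PECAM1 9.04-fold (-3.18 ± 0.51). The others that fell by the same rule were LDB2, A2M, GMFG, ANKRD1 and FMO2. The kinetochore gene CENPF rose 4.82-fold (2.27 ± 0.57, p = 0.0262, higher in 14 of 15) and MMP13 by 1.84 ± 0.50 (p = 0.0403). OCIAD2, MND1, LRIG3, SNORD28, DLGAP5, ERO1A, NET1 and DTL rose too, each higher in 14 of 15 patients.

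Of the 21 endothelial genes 20 fell in microdissected tumors (median -1.50, p = 0.000105), with FCN3 at -2.36 ± 0.33. Alveolar type II genes fell in 6 of 13 (11 adjusted over the list alone, median -1.51, p = 0.000126), with WIF1 at -2.91 ± 0.42. Type I genes fell in 7 of 11 (9 adjusted over the list alone, median -1.46, p = 0.000126), with CAV1 at -2.37 ± 0.57. Macrophage genes fell in 14 of 17 (median -1.35, p = 0.000105), with TYROBP at -1.35 ± 0.20. T and NK cell genes fell in 5 of 14 (8 adjusted over the list alone, median -0.66, p = 0.000126), with CD3E higher in 0 of 15 patients (-0.69 ± 0.14) and NKG7 at -1.21 ± 0.18. MHC class II genes fell in 3 of 6 (6 adjusted over the list alone, median -1.01, p = 0.000691), with HLA-DPA1 at -1.89 ± 0.43. Immediate early genes fell in 8 of 15 (median -1.10, p = 0.000691), with DUSP1 at -2.01 ± 0.28. Smooth muscle genes fell in 2 of 10 (6 adjusted over the list alone, median -0.67, p = 0.00247). Proliferation genes rose in 16 of 34 (34 adjusted over the list alone, median 0.87, p = 0.00184), with BUB1B at 1.80 ± 0.40 and CDC6 at 1.57 ± 0.33. Histones rose in 2 of 14 (median 0.40, p = 0.00186), with H2AC4 at 0.61 ± 0.15. These 10 lists also passed with an estimated correlation (adjusted p from 0.0177 to 0.0486).

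A further 8 lists passed in microdissected tumors but not with an estimated correlation. Hypoxia and glycolysis genes rose in 3 of 17 (9 adjusted over the list alone, median 0.65, p = 0.0113, and adjusted p = 0.108 with an estimated correlation), with LDHA at 1.23 ± 0.26. Metalloproteinases rose in 2 of 9 (median 0.51, p = 0.00309, and adjusted p = 0.0594 with an estimated correlation), with MMP12 at 1.12 ± 0.31. Of the basal and squamous genes PERP rose (1.22 ± 0.33) and 12 passed adjusted over the list alone (median 0.91, p = 0.014, and adjusted p = 0.108 with an estimated correlation). The NRF2 list had 0 called members (median 0.61, p = 0.0242), and the respiratory chain list 1 (median 0.37, p = 0.0181), with adjusted p = 0.121 and adjusted p = 0.119 with an estimated correlation. Mast cell genes (0 called, median -0.17, p = 0.014), neutrophil genes (0 called, median -0.28, p = 0.0288) and erythroid genes (2 fell, median -0.26, p = 0.015) had adjusted p = 0.108, 0.116 and 0.121 with an estimated correlation. The matrix list did not move one way (median 0.09, mean -0.12, p = 0.844) while its mixed test passed (p = 4.72e-05), and DCN (-2.33 ± 0.55) and FN1 (-1.55 ± 0.37) were among 3 members that fell. Ciliated, airway secretory, glandular, B and plasma cell and interferon lists did not pass (medians -0.07, -0.06, 0.22, -0.06 and -0.09).

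In limma, 1338 probe sets were called between microdissected tumor and non-tumor lung, 514 higher and 824 lower, naming 1063 distinct genes, and 170 rose and 419 fell by 2-fold or more. The difference of 1 of the 15 patients ran against the others (correlation across genes -0.41), and 2326 were called without this patient. Without adenosquamous samples 886 were called, without the patient as a block 2363 and with the patient as a random effect 2797.

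Microdissected bronchial tissue was set apart by genes of motile cilia. CLXN, a calaxin gene of ciliary motors, was higher in bronchial tissue than in non-tumor lung (4.23 ± 0.68, 5 bronchial and 19 non-tumor samples, 4 pairs, p = 0.00359, higher in 3 of 4) and fell by 4.24 ± 0.68 in tumors against bronchial tissue (p = 0.00341, 4 of 4). RSPH1, a radial spoke gene, was higher in bronchial tissue than in non-tumor lung by 4.00 ± 0.88 (p = 0.0243), and ENKUR, CFAP95 and CFAP43 were raised by 3.99, 3.87 and 3.86. CFAP43, ENKUR, CFAP276 and ZBBX were lower in tumors, with differences of -4.37, -4.22, -4.06 and -4.03. The level of CLXN in non-tumor lung was 2.65 ± 0.77 (SD), near the 5th percentile of microdissected arrays (2.25) and not shown to lie above background, so no fold is given for these genes. Without the patient whose difference ran against the others CLXN remained called against non-tumor lung (3.57, p = 0.0293), while RSPH1 (3.36, p = 0.126), ENKUR, CFAP95 and CFAP43 did not, nor any gene named here for tumors against bronchial tissue (CLXN -3.59, p = 0.0621). Of 19 ciliated genes 13 were higher in bronchial tissue than in non-tumor lung (18 adjusted over the list alone, median 1.99, p = 0.00144, and adjusted p = 0.0751 with an estimated correlation), with DNAI1 at 2.79 ± 0.51 and DRC1 at 2.29 ± 0.36. In tumors against bronchial tissue 14 were lower (18 adjusted over the list alone, median -2.02, p = 0.00093, and adjusted p = 0.0241 with an estimated correlation), the 1 list of 24 that passed there.

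Genes of the alveoli and of other tissue were lower in bronchial samples than in non-tumor lung. The alveolar type II gene PGC lay 11.9-fold lower (-3.58 ± 0.86, p = 0.0412, 4 of 4), RTKN2 8.32-fold, the matrix protein SPARC 7.39-fold (-2.89 ± 0.62, p = 0.0202, 4 of 4), and LDB2 and SCARNA10 had differences of -2.66 each. The type II list (2 members called, median -1.55, p = 0.0198) and the endothelial list (1 called and 19 adjusted over the list alone, median -1.44, p = 0.0196) had adjusted p = 0.159 with an estimated correlation. The type I list (1 called, median -1.25), the matrix list (2 called, median -0.43), the mast cell list (0 called, median -0.42) and the airway secretory list (0 called, median 0.81) each passed at p = 0.043, and had adjusted p = 0.204 with an estimated correlation. NREP (1.85 ± 0.42, p = 0.039), LRP6 (1.15 ± 0.21, p = 0.00827), TAS2R14, CEP295 and ACACA were higher in tumors than in bronchial tissue, each in 4 of 4 pairs.

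In limma, 414 probe sets were called between bronchial tissue and non-tumor lung (331 higher) and 263 between tumors and bronchial tissue (12 higher). On 1 of the 5 bronchial arrays ciliated genes were at the level of non-tumor lung (list mean 3.99, the other bronchial arrays between 6.14 and 7.53), and without it 570 and 514 were called. Without the patient whose difference ran against the others the counts were 245 (112 higher and 133 lower) and 15. Without replicates 15, 20 and 27 in turn they were 157, 175 and 290, and 76, 161 and 166. Without the patient as a block they were 1150 and 606.

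**Figure D3:**
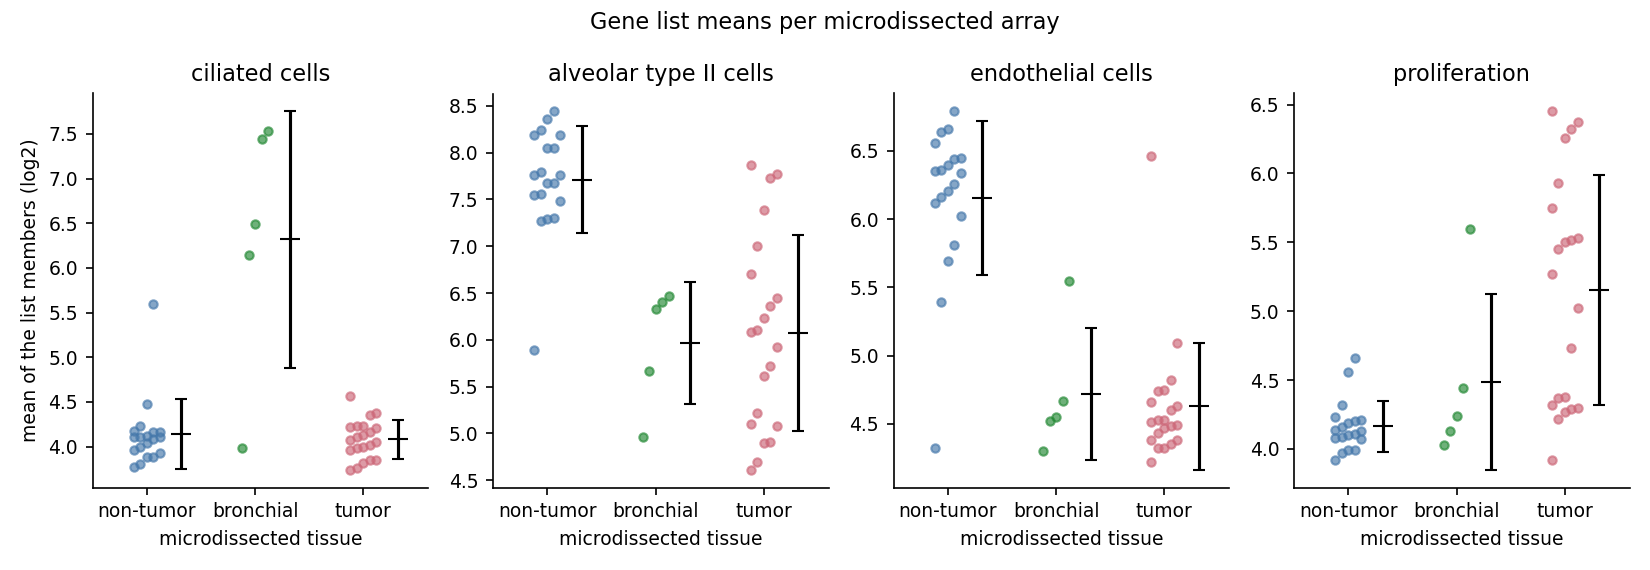
Mean log2 value of the ciliated, alveolar type II, endothelial and proliferation lists on each microdissected array (points) of non-tumor lung (n = 19), bronchial tissue (n = 5) and tumor (n = 21), with the mean and SD as bars. Ciliated list means were 4.14 ± 0.39 (SD), 6.32 ± 1.43 and 4.08 ± 0.21, and proliferation list means 4.16 ± 0.19, 4.49 ± 0.64 and 5.15 ± 0.84.

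In amplified macrodissected tissue SPP1 rose 22.1-fold in tumors (4.47 ± 0.44, n = 10 pairs, p = 0.00034, 10 of 10 patients). The glutathione peroxidase GPX2 rose by 3.57 ± 0.60 (p = 0.0068, 9 of 10) and the macrophage elastase MMP12 by 2.84 ± 0.44 (p = 0.00472, 10 of 10). Their non-tumor levels of 3.54 and 3.28 lay near the 5th percentile of the arrays (2.24), so no fold is given for them. CENPF rose 6.52-fold and the quinone reductase NQO1 5.20-fold (2.38 ± 0.27, p = 0.000774, 10 of 10). SPRR2A, PI3, UCHL1, TOP2A (2.35 ± 0.44) and SPINK1 were the others that rose by the same rule. The level of SFTPC changed by -4.59 ± 0.53 (p = 0.000833, 10 of 10). FABP4 fell 17.2-fold (-4.10 ± 0.25, p = 2.35e-05, 10 of 10) and the water channel AQP4 9.11-fold (-3.19 ± 0.41). The club cell gene SCGB1A1 fell 7.18-fold (-2.84 ± 0.61, p = 0.0225, 9 of 10), and FMO2, ABI3BP, SCN7A, WIF1, LIFR and the complement gene C7 fell by 2.95 or more on the log2 scale.

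Alveolar type I genes fell in 7 of 11 (median -1.91, p = 9.73e-06), type II genes in 8 of 13 (median -1.74, p = 0.000336) and endothelial genes in 17 of 21 (median -1.39, p = 9.73e-06) of amplified macrodissected tumors, with CLIC5 at -1.96 ± 0.13, LAMP3 at -2.11 ± 0.32 and EMCN at -2.58 ± 0.19. These 3 lists also passed with an estimated correlation (adjusted p = 0.0129, 0.0258 and 0.0129). Proliferation genes rose in 27 of 34 (median 1.14, p = 0.00115), histones in 7 of 14 (median 0.61, p = 0.00115). NRF2 targets rose in 5 of 16 (median 0.85, p = 0.00182) and the respiratory chain in 1 of 14 (median 0.26, p = 0.00115), and macrophage genes fell in 8 of 17 (median -1.13, p = 0.00115). These 5 lists had adjusted p = 0.0574 with an estimated correlation. Metalloproteinases (1 of 9 rose, median 0.73, p = 0.0033) and mast cell genes (1 of 7 fell, median -0.32, p = 0.00349) had adjusted p = 0.0612 with an estimated correlation. Smooth muscle genes fell in 5 of 10 (median -0.71, p = 0.00374, and adjusted p = 0.0661 with an estimated correlation), neutrophil genes in 2 of 9 (median -0.47, p = 0.00676, and adjusted p = 0.0782 with an estimated correlation) and erythroid genes in 2 of 6 (median -0.13, p = 0.0151, and adjusted p = 0.135 with an estimated correlation). Hypoxia and glycolysis genes rose in 6 of 17 (median 0.84, p = 0.00374, and adjusted p = 0.0816 with an estimated correlation), with GAPDH at 1.36 ± 0.23. Basal and squamous genes rose in 2 of 17 (16 adjusted over the list alone, median 1.93, p = 0.0131), and ciliated genes fell in 3 of 19 (median -0.25, p = 0.0145) and immediate early genes in 5 of 15 (median -0.60, p = 0.0126), each with adjusted p = 0.113 with an estimated correlation. The matrix list did not pass (4 rose and 1 fell, median 0.73, p = 0.0518), though CTHRC1 rose in 10 of 10 patients (1.09 ± 0.16) and SULF1 by 2.00 ± 0.41. Nor did the MHC class II list (median -0.84, p = 0.0931), the glandular list (median -0.03, mean 0.21) or the other 4.

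In limma, 1609 probe sets were called in amplified macrodissected tissue, 648 higher and 961 lower, and 185 rose and 457 fell by 2-fold or more. Within the 2 array sets of 6 and 4 patients 531 (67 higher) and 195 (80 higher) were called. The medians in set 1 and set 2 were -1.22 and -1.52 for endothelial, -0.96 and -2.73 for type II, and 0.53 (p = 0.282) and 3.65 (p = 0.000136) for basal and squamous genes. Macrophage (-0.57, p = 0.0509) and hypoxia genes (0.52, p = 0.0938) did not pass in set 1. Smooth muscle (-0.65, p = 0.197), metalloproteinase (1.09, p = 0.105), mast cell (-0.40, p = 0.102), neutrophil (-0.44, p = 0.138) and ciliated genes (-0.06, p = 0.161) did not pass in set 2. Immediate early (-0.35, p = 0.104, and -0.92, p = 0.138) and erythroid genes (-0.12, p = 0.19, and -0.24, p = 0.0758) passed in neither. MHC class II genes passed in set 2 alone (-0.05, p = 0.977, against -2.04, p = 0.0207), as did glandular genes (0.35, p = 0.269, against -0.37, p = 0.0352). All 4 patients of set 2 had squamous cell carcinoma, so set and histology cannot be told apart for these differences. Of the calls with a 2-fold difference, 28 higher and 132 lower probe sets were shared by all 3 sample types, which share patients. Macrodissected and microdissected tissue shared 33 higher and 141 lower (0.7 and 3.7 if independent), and 0 had opposite directions. Between patients without overlap, mean differences correlated across genes, which are not replicates, at Pearson r = 0.623 (Spearman 0.518) for amplified against macrodissected tissue and 0.624 (0.532) for microdissected against macrodissected tissue.

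**Figure D4:**
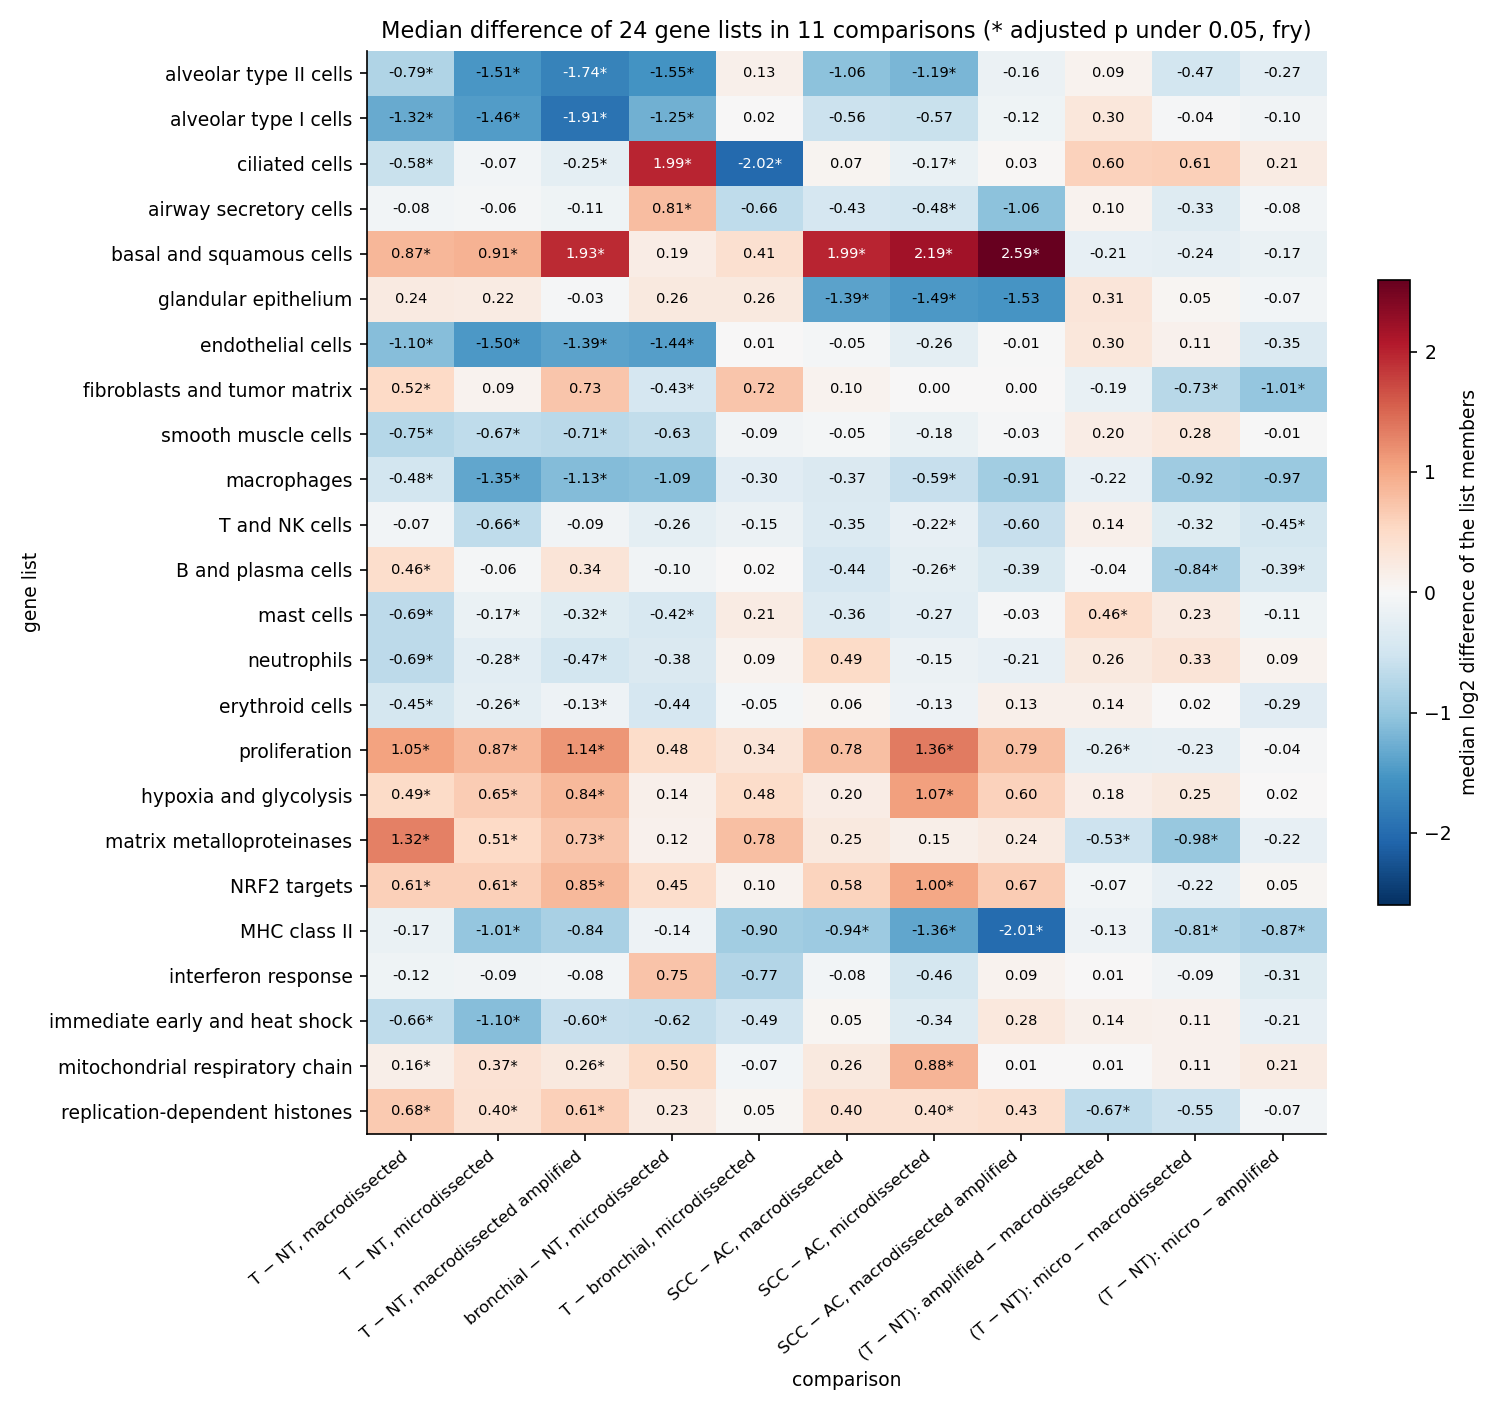
Median log2 difference of each of the 24 gene lists (lines of the map) in 11 comparisons (columns), with colour for the size and direction and a star where the adjusted p of fry is under 0.05. Endothelial and alveolar lists are lower and the proliferation list higher in tumors of all 3 sample types, with endothelial medians of -1.10, -1.50 and -1.39 in macrodissected, microdissected and amplified macrodissected tissue.

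Squamous cell carcinoma and adenocarcinoma differed in macrodissected tumors in genes of stratified and of glandular epithelium. The basal cell keratin KRT5 had a level of 10.90 ± 2.78 (SD, n = 11) in squamous cell carcinoma and 7.15 ± 0.59 (n = 18) in adenocarcinoma, a 13.4-fold difference (3.75 ± 0.64, p = 0.00308). The desmosomal cadherin DSG3 was higher by 4.25 ± 0.67 (p = 0.00186), DSC3 by 4.17 ± 0.67, and SERPINB5 and SERPINB13 by 3.22 each. The adhesion molecule CEACAM6 was 6.09-fold lower in squamous cell carcinoma (-2.61 ± 0.43, p = 0.00289), as were SPINK1 (-2.70 ± 0.74, p = 0.0415), the protease gene NAPSA (-2.33 ± 0.56), MUC21 and AFAP1-AS1. Of 17 basal and squamous genes 16 were higher (median 1.99, p = 4.39e-05, and adjusted p = 0.0224 with an estimated correlation), and the mean of the list lay above every adenocarcinoma in 8 of 11 squamous cell carcinomas. Of 15 glandular genes 12 were lower (14 adjusted over the list alone, median -1.39, p = 3.27e-06, and adjusted p = 0.00222 with an estimated correlation), among them MUC1 (-1.81 ± 0.32) and KRT7 (-1.36 ± 0.27). All 6 MHC class II genes were lower (median -0.94, p = 0.00182, and adjusted p = 0.074 with an estimated correlation), with CIITA, their transcriptional activator, at -0.67 ± 0.14.

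In limma, 1007 probe sets were called (544 higher), and 1984 without the patients whose difference ran against the others. KRT5, DSG3 and DSC3 then differed by 4.69, 5.18 and 5.14, and SPINK1 was no longer called (p = 0.0562). Within array set 1 (8 against 8) 35 were called (9 higher) and within set 2 (3 against 10) 724 (577 higher), and 1020 with the set as a covariate. Both patients whose difference ran against the others lie in set 1, among its 8 squamous cell carcinomas. The basal and squamous medians were 1.95 (p = 0.0293) and 2.54 (p = 0.00357) within the sets, the glandular medians -1.28 (p = 0.00659) and -1.71 (p = 0.00357), while the MHC class II medians were -0.83 (p = 0.356) and -1.11 (p = 0.00736). In macrodissected non-tumor lung (10 and 19 patients), limma called 0 probe sets between the histologies (4921 at an unadjusted p under 0.05) and 0 of 24 lists passed, with KRT5 at -0.20 ± 0.39. Within set 1 of the non-tumor samples limma called 2, and within set 2 (2 against 11) 0, with 1400 at an unadjusted p under 0.05.

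The tumor minus non-tumor change itself differed between histologies in 193 probe sets (122 higher and 71 lower in squamous cell carcinoma, 10 against 18 patients). DSG3 changed by a mean of 3.81 in squamous cell carcinoma and -0.02 in adenocarcinoma (difference 3.83 ± 0.72, p = 0.00997), KRT5 by 3.32 and -0.44 (3.76 ± 0.71, p = 0.0104) and DSC3 by 3.57 and -0.31, and CLCA2 and SERPINB5 followed. CEACAM6 changed by -1.68 and 0.81 (-2.49 ± 0.48, p = 0.0104), the membrane mucin MUC1 by -1.05 and 0.59, and the transporter ABCC3 by -0.06 and 1.61 (-1.67 ± 0.25, p = 0.00196), followed by STK32A and KCNK5. Both the basal and squamous list (9 of 17 called and 17 adjusted over the list alone, median 1.87, p = 0.000524) and the glandular list (2 of 15 called and 14 adjusted over the list alone, median -1.30, p = 4.03e-05) differed, with adjusted p = 0.0125 and 0.00368 with an estimated correlation. The count was 895 without the patients whose difference ran against the others, with DSC3 at 5.15, DSG3 at 4.92 and STK32A no longer called (p = 0.0521). It was 90 with the array set as a covariate, and 11 and 57 within the sets, set 1 holding both of these patients. Within set 1 the basal and squamous median was 1.99 (p = 0.0718) and within set 2 2.01 (p = 0.0406).

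**Figure D5:**
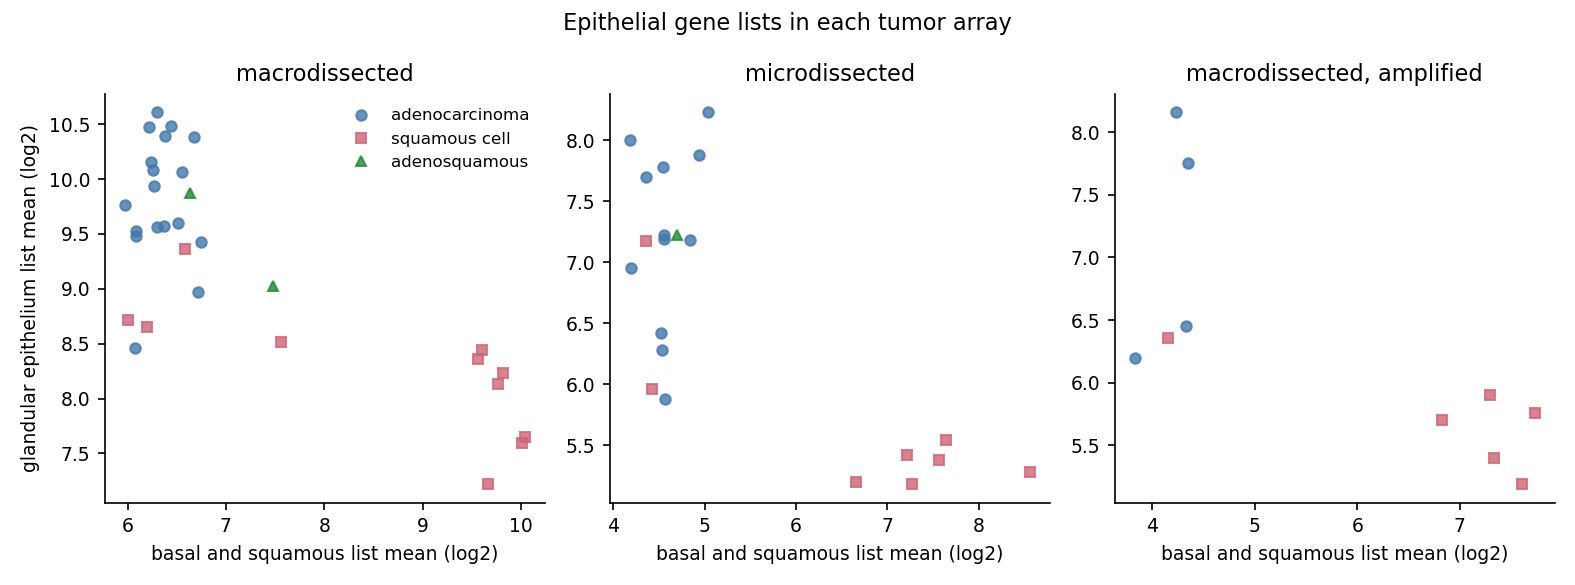
Mean log2 value of the basal and squamous list (horizontal axis) and of the glandular list (vertical axis) in each tumor, 1 panel per sample type, coloured by histology. The basal and squamous mean was 8.62 ± 1.66 (SD) in 11 squamous cell carcinomas and 6.35 ± 0.23 in 18 adenocarcinomas of macrodissected tissue, and 6.71 ± 1.53 (n = 8) and 4.57 ± 0.27 (n = 12) of microdissected tissue.

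In microdissected tumors the same comparison (8 squamous cell carcinomas, 12 adenocarcinomas) showed KRT5 13.7-fold higher (3.78 ± 0.73, p = 0.00949) and CRYAB higher by 3.29 ± 0.62. DSG3 (4.14 ± 0.78, p = 0.0091), the neuropeptide NTS (3.92 ± 0.91) and DSC3 (3.87 ± 0.73) were higher too, from adenocarcinoma levels of 3.41, 2.52 and 3.38 near the 5th percentile of the arrays (2.25), so no fold is given for them. The phosphate transporter SLC34A2 of alveolar type II cells was 23.9-fold lower (-4.58 ± 0.58, p = 0.00083), the surfactant gene SFTPB 13.1-fold (-3.71 ± 0.59), STEAP4 by a difference of -4.41 ± 0.42 (p = 3.01e-05), and PIGR and CYP2B7P had differences of -3.60 and -3.51. Basal and squamous genes were higher in 9 of 17 (15 adjusted over the list alone, median 2.19, p = 0.000698). Proliferation genes were higher in 20 of 34 (median 1.36, p = 0.000264), with PCNA at 1.67 ± 0.28 and TPX2 at 2.51 ± 0.43. Respiratory chain genes were higher in 4 of 14 (median 0.88, p = 0.000698), with NDUFB5 at 2.04 ± 0.39. Glandular genes were lower in 5 of 15 (11 adjusted over the list alone, median -1.49, p = 9.47e-05), with MUC1 at -2.97 ± 0.41, and alveolar type II genes in 6 of 13 (median -1.19, p = 9.47e-05). These 5 lists also passed with an estimated correlation (adjusted p from 0.0261 to 0.0299).

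A further 9 lists passed between the microdissected histologies but not with an estimated correlation. Hypoxia and glycolysis genes were higher (3 of 17 called, median 1.07, p = 0.00512, and adjusted p = 0.0634 with an estimated correlation), as were histones (2 of 14, median 0.40, p = 0.00512, and adjusted p = 0.0568 with an estimated correlation) and NRF2 targets (0 of 16, median 1.00, p = 0.0348, and adjusted p = 0.122 with an estimated correlation). MHC class II genes were lower (3 of 6, median -1.36, p = 0.00261, and adjusted p = 0.0947 with an estimated correlation), with HLA-DPA1 at -2.59 ± 0.61. Secretory genes (2 of 12, median -0.48, p = 0.00531) and B and plasma cell genes (0 of 10, median -0.26, p = 0.00454) were lower, each with adjusted p = 0.122 with an estimated correlation. Macrophage (median -0.59, p = 0.0452) and T and NK cell lists (median -0.22, p = 0.0386), with 0 called members each, had adjusted p = 0.35, and the ciliated list (0 called, median -0.17, p = 0.0416) adjusted p = 0.37 with an estimated correlation. In limma 874 probe sets were called (630 higher).

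In amplified macrodissected tumors (6 and 4) lysozyme (LYZ) was 8.58-fold lower in squamous cell carcinoma (-3.10 ± 0.45, p = 0.0445), and TARP, the MHC class II chaperone HLA-DMB (-2.33 ± 0.37, p = 0.0473), KLRB1 and IQGAP2 were lower (-2.38 to -2.20), while EBPL was higher by 0.85 ± 0.13. The MHC class II list was lower (1 of 6 called and 5 adjusted over the list alone, median -2.01) and the basal and squamous list higher (0 of 17 called and 16 adjusted over the list alone, median 2.59), both at p = 0.0351, with adjusted p = 0.361 with an estimated correlation. With the array set as a covariate neither passed (medians -1.30 and 1.00, p = 0.49 each). In limma 50 probe sets were called (1 higher). With the array set as a covariate 0 were called (3328 at an unadjusted p under 0.05), and within set 1 (4 adenocarcinomas, 2 squamous cell carcinomas) limma called 0 (3917 at an unadjusted p under 0.05). Set 2 held squamous cell carcinoma alone. Without replicate 6, 7, 13 or 4, each leaving 3 adenocarcinomas, limma called 0, 0, 1 and 59 (4185, 4199, 5422 and 5851 at an unadjusted p under 0.05). Patients with squamous cell carcinoma were not left out.

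The sample types were compared through their tumor minus non-tumor differences in shared patients. Matrix genes had lower tumor effects in microdissected than in macrodissected tissue (median difference -0.73, 0 of 21 called and 15 adjusted over the list alone, p = 0.00501, n = 15), with SPARC at -1.56 ± 0.30 and MMP11 at 0.08 against 1.38 (-1.30 ± 0.22, p = 0.0568). B and plasma cell genes (-0.84, 0 of 10 called and 8 adjusted over the list alone, p = 0.00501) and metalloproteinases (-0.98, 0 of 9 called and 7 adjusted over the list alone, p = 0.00428) had lower effects too. The 3 lists had adjusted p = 0.0501 with an estimated correlation. MHC class II genes had a median of -0.81 (0 of 6 called, p = 0.0418, and adjusted p = 0.173 with an estimated correlation). Limma called 2 probe sets, the microRNA gene MIR27A (-0.20 against -1.47, difference 1.27 ± 0.15, p = 0.00441, 14 of 15 patients) and the growth factor receptor FGFR4 (-0.22 against -1.48, 1.26 ± 0.17, p = 0.0135, 13 of 15). At an unadjusted p under 0.05 it called 3814. Without the patients whose difference ran against the others 636 were called, and with probe sets naming 1 gene only 56.

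Microdissected and amplified macrodissected tissue shared 7 patients with tumor and non-tumor lung. The tumor effects of matrix genes were lower in microdissected tissue (median -1.01, 0 called and 12 adjusted over the list alone, p = 0.0295, and adjusted p = 0.0582 with an estimated correlation), with DCN at -2.64 ± 0.47. T and NK cell genes (median -0.45, 0 called, p = 0.0295, and adjusted p = 0.0484 with an estimated correlation) and MHC class II genes (median -0.87, 0 called, p = 0.0295, and adjusted p = 0.0582 with an estimated correlation) were lower too, with IL7R at -1.78 ± 0.33 and HLA-DPA1 at -1.76 ± 0.33. B and plasma cell genes had a median of -0.39 (0 called, p = 0.0474, and adjusted p = 0.147 with an estimated correlation), with JCHAIN at -3.47 ± 0.42. Limma called 0 probe sets, the smallest adjusted p being 0.18, and 1833 at an unadjusted p under 0.05.

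Tumor effects differed between amplified macrodissected and macrodissected tissue, prepared with different kits, in 150 probe sets (106 higher and 44 lower in amplified tissue, n = 10). The tumor effect of the scavenger receptor SCARA5 was -0.08 in amplified macrodissected and -1.42 in macrodissected tissue (1.34 ± 0.13, p = 0.00194, 10 of 10 patients). That of SLC6A4 was -1.88 and -3.23, and NECAB1, MIR27A and NPR1 also had higher values. The mitotic kinase PLK1 had effects of 0.47 and 1.81 (-1.35 ± 0.26, p = 0.0449, 10 of 10), the linker histone H1-5 0.54 and 1.84 (-1.30 ± 0.17, p = 0.00784, 10 of 10) and MMP11 0.40 and 1.69. MYBL2 and PYCR1 had differences of -1.23 each. Histones (5 of 14 lower and 7 adjusted over the list alone, median -0.67, p = 0.00317), metalloproteinases (1 of 9 lower, median -0.53, p = 0.00424) and mast cell genes (2 of 7 higher, median 0.46, p = 0.0011), with HDC at 1.20 ± 0.22 and GATA2 at 0.76 ± 0.14, each had adjusted p = 0.034 with an estimated correlation. Proliferation genes (3 of 34 lower, median -0.26, p = 0.0497) had adjusted p = 0.207 with an estimated correlation. With quantile normalization 96 were called, and with probe sets naming 1 gene only 321.

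The authors' deposited table for macrodissected tissue lists 1349 probe sets, 493 higher and 856 lower in tumors. The authors' deposited tables were selected at a fold difference of at least 2 besides an adjusted p, whereas the calls here use the adjusted p alone. Of the probe sets in the authors' deposited table for macrodissected tissue, 1280 (94.9%) were called here in the same direction, 379 of them with a 2-fold difference, and the median absolute log2 difference was 1.36 in the authors' deposited table and 0.81 here. The values of that authors' deposited table correlated across genes at 0.997 with the differences of the 10 patients who also had amplified arrays and at 0.975 with those of all 30, and the patients the authors used are not given in the sources used here. The median absolute gap to these values was 0.183 for the 10 patients and 0.595 for all 30 (log2). The comparison may therefore set different groups of patients side by side. The authors' deposited table for microdissected tissue lists 835, of which 546 (65.4%) were called here in the same direction, 425 of them with a 2-fold difference. The authors' deposited table for amplified macrodissected tissue lists 728, of which 617 (84.8%) were called here, 529 of them with a 2-fold difference. In none of the 3 authors' deposited tables was a probe set called here in the opposite direction.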

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

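The tests of explanations and the counts of other splits in this part were chosen after the results were seen. In groups of 4 to 10 samples, 17 of 99 groups of a named gene had a sample far from the others by Dixon's ratio, the gap to the nearest sample divided by the range (17.2%), where chance gives about 1 in 20. In 5 bronchial samples, 1 sample lay below the others in 7 genes of cilia. The ratios were 0.799 for CFAP43 (2.89 against 8.39 in the nearest sample, log2), 0.714 for CLXN (2.66 against 7.13), 0.825 for ENKUR (2.81 against 8.48), 0.821 for CFAP276 (4.23 against 9.53), 0.862 for ZBBX (2.70 against 8.28), 0.907 for RSPH1 (4.11 against 9.95) and 0.871 for CFAP95 (2.63 against 8.12). RTKN2 was high in 1 bronchial sample (0.795, 5.89 against 4.18). In 10 amplified macrodissected non-tumor samples, 1 sample was high in PI3 (0.488, nearest other 5.08), UCHL1 (0.504, 4.99 against 4.18) or SPINK1 (0.582, 7.45 against 4.63), and in the 10 tumors 1 was high in FABP4 (0.533, 5.82 against 4.43) or WIF1 (0.609, 8.23 against 5.18). Of 8 microdissected squamous cell carcinomas 1 was high in SFTPB (0.559, 9.41 against 6.35) or CYP2B7P (0.563, 6.38 against 4.49), and of 4 amplified adenocarcinomas 1 was low in HLA-DMB (0.921, 7.25 against 8.43) or high in KLRB1 (0.954, 6.82 against 5.49).

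The tumor minus non-tumor change in macrodissected tissue differed between squamous cell carcinoma and adenocarcinoma by a test of the difference itself in 193 probe sets. Among genes of stratified epithelium the difference was 3.88 for DSC3, 3.83 for DSG3, 3.76 for KRT5, 3.13 for CLCA2 and 3.05 for SERPINB5, and the median of the basal and squamous list was 1.87. It was -2.49 for CEACAM6, -1.67 for ABCC3, -1.64 for MUC1, -1.56 for STK32A and -1.56 for KCNK5, with a glandular median of -1.30.

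Tumor effects differed between sample types in the same patients by a test of the difference. Microdissected minus amplified macrodissected tissue gave medians of -1.01 for matrix genes, -0.45 for T and NK cell genes, -0.39 for B and plasma cell genes and -0.87 for MHC class II genes. With an estimated correlation the T and NK cell list alone passed (adjusted p = 0.0484). Microdissected minus macrodissected tissue differed in 2 probe sets, MIR27A (1.27) and FGFR4 (1.26), and in the matrix (-0.73), B and plasma cell (-0.84), metalloproteinase (-0.98) and MHC class II lists (-0.81). With an estimated correlation these lists had adjusted p = 0.0501, 0.0501, 0.0501 and 0.173, and none of the 24 passed. Amplified macrodissected minus macrodissected tissue, prepared with different kits, differed in 150 probe sets. NECAB1 (1.37), SLC6A4 (1.34), SCARA5 (1.34), MIR27A (1.33) and NPR1 (1.28) were higher, as was the mast cell list (0.46). PLK1 (-1.35), H1-5 (-1.30), MMP11 (-1.29), MYBL2 (-1.23) and PYCR1 (-1.23) were lower, as were the proliferation (-0.26), metalloproteinase (-0.53) and histone lists (-0.67). The proliferation list had adjusted p = 0.207 with an estimated correlation, and the other 3 lists adjusted p = 0.034.

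A signal lay outside the comparisons in the 2 microdissected arrays whose labels give no clear group. The ciliated list had a mean of 7.79 on 1 of them, above every non-tumor lung array (3.77 to 5.60), and 4.13 on the other.

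In 3 patients, 2 macrodissected and 1 microdissected, the tumor minus non-tumor difference ran against that of the others, with correlations across genes of -0.62, -0.48 and -0.41, the lowest of the other patients being 0.06 and 0.13. Little tumor in the tumor piece would leave the non-tumor array in place, and in 3 of 3 patients the array labelled non-tumor lay on the tumor side of the midpoint, so the tables argue against it. A candidate explanation is tissue labels exchanged within the pair, since in 3 of 3 patients both arrays lay on the wrong side. As these patients were chosen by a reversed difference, the order of their 2 arrays is largely built in. On the axis from non-tumor to tumor, the arrays labelled non-tumor scored 0.93 (microdissected), 1.42 and 0.55 (macrodissected), the last near the midpoint. Non-tumor arrays of the other patients scored at most 0.33 and 0.32, and their tumor arrays had medians of 0.91 and 0.94. The patient at 0.55 had no pair by another method. For the remaining patients, measured by another method, the correlations with the others were 0.45 and 0.70. No biological explanation was tested, and the labels were used as given.

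Matrix, metalloproteinase and plasma cell genes had smaller tumor effects after microdissection than in macrodissected tissue by fry (adjusted p = 0.0501 for each list with an estimated correlation, and 0 members called by limma over all genes). The Pico amplification is shared with amplified macrodissected tissue, yet against that tissue the mean shift per patient was -1.11 for matrix genes (exact p = 0.0156, n = 7). It was larger than the -0.22 of amplified minus macrodissected tissue, which argues against the Pico amplification as the whole cause for this list. Against amplified tissue, however, the matrix list did not pass with an estimated correlation. For plasma cell genes amplified minus macrodissected tissue shifted by -0.09 (SD 0.47, exact p = 0.607, n = 10). Microdissected minus macrodissected tissue shifted by -0.78 (SD 0.63, n = 15), in patients that overlap only in part. These values argue against the Pico amplification as the whole cause, but the direct test against amplified tissue cannot decide. The plasma cell shift of -0.70 in that test (exact p = 0.0156, n = 7) rests largely on JCHAIN (without it -0.39, exact p = 0.0469). That difference had adjusted p = 0.147 with an estimated correlation, so its size is left open. For metalloproteinase genes the cause is left open, the shift being -0.34 (exact p = 0.234, n = 7) and that of amplified minus macrodissected tissue -0.66 (exact p = 0.00391). The tables argue against the patients running against the others as the cause, since the median shift of the 3 lists was -0.83 without them and -0.78 with them. Fewer stromal and immune cells in the captured tumor may contribute. More of these cells in the captured non-tumor lung would give the same shift, and levels were not compared between sample types, so the test cannot tell these apart. Against amplified macrodissected tissue 7 of 8 stromal and immune lists had a median below 0, among them the matrix and plasma cell lists that define the pattern. Per patient, only matrix, T and NK, B and plasma cell (exact p = 0.0156 each) and macrophage genes (exact p = 0.0312) shifted. Endothelial (exact p = 0.125), smooth muscle (median -0.01), mast cell (-0.11) and neutrophil genes (0.09) did not, so an equal loss of all these cells is not shown.

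On 1 of 5 microdissected bronchial arrays ciliated genes had a mean of 3.99, against 6.14 to 7.53 on the others. Alveolar lung under a bronchial label does not match it, with 0 of 3 lists nearer to non-tumor lung than to tumor, nor does airway epithelium without cilia, with 0 of 2 lists, secretory (5.26, lowest other 7.43) and basal (4.54, lowest other 4.83), at the level of the other bronchial arrays. An exchange with the tumor array of the same patient would put ciliated genes on that array, where their mean was 4.16. Tumor cells under a bronchial label may be the cause, as the proliferation list had a mean of 5.60, above every other bronchial (up to 4.44) and non-tumor array (up to 4.66).

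Other splits of the samples were counted for each comparison, up to 100 each with the real one. Chance can be excluded for macrodissected tumors (9745 probe sets called, at most 3 in the other splits), microdissected tumors (1338 and 3) and amplified macrodissected tumors (1609 and 2), where in each 1 of 100 splits, the real one, reached the count. The same holds between histologies in macrodissected tumors (1007 and 0), microdissected tumors (874 and 96) and the tumor minus non-tumor change (193 and 14), and for tumor effects in amplified against macrodissected tissue (150 and 2). In microdissected against macrodissected tissue 2 were called and at most 1 in the other splits, a gap of 1 call. Quantile normalization called 1, and no splits were run with it, so chance is left open there. For the bronchial comparisons 16 splits are too few for a share under 0.05, with 263 and 338 for tumors and 414 and 355 for non-tumor lung. In amplified tumors 2 of 100 splits between histologies, the real one among them, called as many as the 50 found. The other one follows the 2 array sets, called 1656 and points to a structure of the samples. All 4 adenocarcinomas lie in set 1, and 0 were called without replicate 6 or 7, so chance is not excluded for histology. With the array set as a covariate 0 were called there by limma, with 3328 at an unadjusted p under 0.05. Between histologies in non-tumor lung and between microdissected and amplified tissue limma called 0 (4921 and 1833 at an unadjusted p under 0.05), which every split reaches by construction (100 of 100 and 64 of 64), so these counts say nothing about chance. The highest other splits called 8254 and 1, and 8254 points to a structure of the samples.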

How the results depend on the processing

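Leaving out patients running against the others, probe sets naming more than 1 gene or the bronchial array low in ciliated genes, and the fits by array set, were alternatives chosen after seeing the data. Of 312 gene list results 95 passed with fry. Under the alternatives other than an estimated correlation and a random patient effect, 53 of the 95 were never lost. These alternatives gave 2904 values, of which 96 no longer passed, 61 passed in addition and 0 reversed. With camera, at an estimated correlation, 27 of the 95 passed and 68 did not, and 25 passed under every alternative run on gene lists. Camera also compares a list with the other genes. The 68 therefore do not show that correlation alone accounts for the fry results. The named genes gave 128 results, each a gene in 1 comparison, so that a gene can count more than once. Of their 1285 values 1036 kept the call and 249 lost it, and 43 results were never lost. Unless a cause is named, the cause was not tested.

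A threshold of 0.01, stricter by construction, called 6312 probe sets for tumor against non-tumor lung in macrodissected, 376 in microdissected and 408 in amplified macrodissected tissue. It called 110 for tumor against bronchial and 111 for bronchial against non-tumor tissue. Between histologies it called 111 in macrodissected, 143 in microdissected and 0 in amplified tumors by limma, and 35 for the change. For tumor effects it called 1 between microdissected and macrodissected and 17 between amplified and macrodissected tissue. Of the probe sets in the authors' deposited table for microdissected tissue 265 were then called, and 295 of those in the authors' deposited table for amplified tissue.

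Treating paired samples as unpaired (no replicate block) called 2363 in microdissected tumor against non-tumor lung, 606 against bronchial tissue and 1150 for bronchial tissue against non-tumor lung, and the patient as a random effect 2797, 646 and 1257. Both also draw on samples without a partner. Without the block 6 named genes and 1 list no longer passed, MMP13 (1.35) in microdissected tumors, TAS2R14, PGC and SCARNA10 in the bronchial comparisons, and SPINK1, SCGB1A1 and the ciliated list in amplified tumors, and 7 lists passed in addition. The counts of the other 2 paired comparisons stayed within 1.5 times. Leaving out the third of probe sets with the lowest mean called 107 and 245 in the bronchial comparisons and 12 between microdissected and macrodissected effects. Quantile normalization called 21 between histologies in amplified tumors, 1 between microdissected and macrodissected effects and 96 between amplified and macrodissected effects. An intensity trend with a robust prior called 30 between histologies in amplified tumors. Probe sets naming 1 gene gave 3, 56 and 321 for microdissected against amplified, microdissected against macrodissected, and amplified against macrodissected effects, with fewer probe sets tested.

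With fewer samples, leaving out each of the 5 patients with bronchial tissue in turn gave 15 to 491 for tumor against bronchial and 157 to 560 for bronchial against non-tumor tissue, and leaving out each of the 4 with adenocarcinoma gave 0 to 59 between histologies in amplified tumors. Without adenosquamous patients 886 were called in microdissected tumors. Without patients running against the others 2326 were called in microdissected tumor against non-tumor lung, 15 against bronchial tissue, 245 between bronchial and non-tumor tissue, 1984 and 1 between histologies in macrodissected tumor and non-tumor lung, 895 for the change and 636 between microdissected and macrodissected effects. Without the bronchial array low in ciliated genes 514 were called for tumor against bronchial tissue.

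The array set as a covariate gave 90 for the change between histologies and 0 between histologies in amplified tumors by limma. Within set 1 (16 pairs), tumor against non-tumor lung gave 827 in macrodissected tissue, and within set 2 (14 pairs) 7656. The number of pairs alone therefore does not account for the low count in set 1. Both macrodissected patients running against the others lie in set 1. In amplified tissue, with fewer samples, set 1 gave 531 and set 2 gave 195. Between histologies set 1 gave 35 in macrodissected tumors, 2 in non-tumor lung and 0 in amplified tumors, and for the change 11 (57 in set 2).

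With an estimated correlation the gene lists passing of 24 were 0 for macrodissected, 10 for microdissected and 3 for amplified tumor against non-tumor lung, 0 for bronchial against non-tumor tissue, 5 and 0 between histologies in microdissected and amplified tumors, 1 between microdissected and amplified effects and 0 between microdissected and macrodissected effects. The share of higher probe sets between microdissected histologies was 72.1% and 62.5% after quantile normalization. The planned comparisons of absolute levels between sample types, and their alternatives, were not run because the sample types have different scales. The median signal was 7.05 on macrodissected, 4.63 on microdissected and 4.42 on amplified arrays, and genes near the background of an array are measured less precisely.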

Other observations

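Histone and proliferation genes were set side by side in the 10 patients with amplified macrodissected and macrodissected tissue, a test chosen after the results were seen. The mean tumor effect of the histone list was 1.28 in macrodissected and 0.67 in amplified macrodissected tissue, and that of the proliferation list 1.55 and 1.23. The histone list lost more than the proliferation list in 9 of 10 patients (mean -0.29 ± 0.22, SD, exact p = 0.00391, two-sided, the smallest possible being 0.00195). The shift of the mast cell list was 0.40 ± 0.16 (SD, exact p = 0.00195, n = 10) and that of the ciliated list 0.60 ± 0.75 (SD, exact p = 0.00391, 9 of 10 above 0), though the ciliated list did not pass fry (adjusted p = 0.123).

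Against amplified macrodissected tissue, the tumor effect of erythroid genes in microdissected tissue had a mean shift below 0 in 7 of 7 patients (-0.78 ± 0.99, SD), and that of MHC class II genes a mean shift of -0.94 ± 0.59, also SD (exact p = 0.0156 each, the smallest possible). The erythroid shift rests on HBB (-3.33 ± 0.51, higher in 0 of 7), while HBD (-0.24), ALAS2 (-0.41) and AHSP (-0.12) were higher in 4 of 7, and the list did not pass fry (adjusted p = 0.542). Means of the proliferation (-0.01), hypoxia (0.02) and NRF2 lists (0.03) lay near 0.

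The microdissected array without a clear group that had a ciliated mean of 7.79 had lower means of the alveolar type II list (6.36 against 8.07) and of the endothelial list (4.33 against 5.96) than the other one. Bronchial arrays had type II means of 4.96 to 6.47, and non-tumor lung 5.89 to 8.44.

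The differences in the authors' deposited table for macrodissected tissue correlated across genes at 0.997 with those of the 10 patients who also had amplified arrays, at 0.975 with all 30 patients and at 0.908 with the others. For microdissected tissue the authors' deposited table gave 0.997 for the 7 patients with amplified arrays and 0.978 for all 15.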
